A study of Homo sapiens with 6 samples.

How the data were processed

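RNA sequencing libraries were made from EndoC-βH1 cells, an established line of human pancreatic β-cells, after transfection with a small interfering RNA (siRNA) at 30 nM. Per the labels, 3 libraries came from cells given a negative control siRNA and 3 from cells given siRNA against STAT3, a transcription factor that carries signals from cytokine receptors of the IL-6 family. The labels do not say whether the STAT3 siRNA was a single sequence or a pool, and its sequence is not given in the sources used here. They name a kit for stranded mRNA libraries. Each library was assigned to its group by the siRNA named in its label and carries a replicate number from 1 to 3 in its title.

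The deposited values are a normalized score, not raw counts: gene counts that the authors scaled to 20000000 (20 M) per library and rounded up to whole numbers. The table holds 58302 Ensembl genes, with whole numbers in every cell. Library totals lie between 20016816 and 20019486, and the excess over 20 M is 0.455 to 0.501 per gene above 0, as rounding up gives. STAR, HTSeq, limma and the genome build GRCh38 are named in the submitters' processing notes, with neither versions nor roles. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Reads from overlapping genes on opposite strands are therefore treated as uncertain. Of the gene identifiers, 58039 matched GENCODE release 29 on GRCh38, from which symbols, positions, transcript lengths and 3' untranslated regions (UTRs) were taken. A spreadsheet had turned 27 gene symbols into dates, and all 27 were restored through the identifiers.

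Rounding up leaves gaps among the low values whose spacing depends on how many reads 1 unit stands for. From these gaps the depth behind the table was estimated as 26.15, 27.64 and 22.74 M reads in genes for control libraries 1, 2 and 3, and 35.57, 34.58 and 23.91 M for STAT3 siRNA libraries 1, 2 and 3. Several depths gave almost equal gaps, and the one that left the low values smoothest was taken. In 5 libraries it was also the depth with the highest likelihood of the gaps, by at least 46.7 log units. In control library 3 a depth of 42.74 M had a likelihood higher by 8.1 log units, but left less smooth low values (deviance per degree of freedom 6.02 against 0.83) and predicted an excess from rounding of 18009, against 17273 at 22.74 M and 17149 in the table. Whole reads could not be recovered exactly, so no count model was run on them. Within each group the libraries differed by more than sampling noise, with a mean chi-square per gene of 8.26 to 23.97 between pairs of libraries of a group. None was therefore treated as a copy of another.

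Genes with a mean of at least 20 per 20 M over the 6 libraries, which is 1 in 1 M, were tested, 20799 in all. Values were taken to log2(value + 10), and a linear model with the group as its only term was fitted to each gene in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a mean-variance trend. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(value + 10) scale, which understates the change of genes with low values. Errors given as SE are limma's standard errors of the log2 fold change, and SDs are over the 3 libraries of a group. Adjusted p-values without another name are from this limma fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the table, the sequence search and the plots.

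The titles give both groups the same replicate numbers, and libraries with the same number also share a date-like code. Deviations from the group means correlated between libraries of the same number at 0.64, 0.90 and 0.79 for replicates 1, 2 and 3, all above 0.1. Between unlike numbers the correlation ran from -0.77 to 0.39. Control library 1 with STAT3 siRNA library 3 (0.39) and control library 3 with STAT3 siRNA library 1 (0.2) were also above 0.1. Each library correlated most with the one of its own number. The numbers were therefore taken to pair the libraries. A fit with the replicate number as a block was run beside the main one, and its values are given where they change a call or move a count by more than 1.5 times. The labels do not say outright that the replicates were separate cultures, so p-values measure the spread between these libraries, which may in part be technical.

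A list of 26 gene groups was fixed before the data were examined, and 24 of them had at least 5 tested members. Each was tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry (a test of a common direction, meant where fry is given without another word, and a test of change in either direction), and p-values were adjusted over the 24 lists. Members were also counted over all tested genes and adjusted over the list alone. A further 5 lists were drawn up after the results were seen and serve the closing observations only.

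The genes named were chosen by a rule fixed in advance. It takes STAT3 and STAT1, and the 12 largest rises and 12 largest falls at an adjusted p under 0.05. The latter need a mean of at least 100 per 20 M, groups that do not overlap, and a symbol that is not a clone-style or locus-only name. It further takes up to 4 members of each fixed list with the smallest p among those past the threshold, or 2 with the smallest p where none passed. INS, IAPP, PDX1, NKX6-1, MAFA, GCG, SST, SOCS3, HLA-A, CXCL10, MX1 and BCL2L1 were named whatever their p. Where another expressed gene overlaps a named one, this is said beside its values.

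The fits were tested on simulated data for this comparison, with 20799 genes, 3 libraries per group and the pairing of the real ones. In the fit without a block, 0% of genes changed by 1.25-fold were recovered, 12% at 1.5-fold, 54% at 2-fold and 72% at 4-fold, with 0 false calls. With the block the shares were 64%, 82%, 100% and 100%, with 14 false calls, or 7.5% of all calls. Every simulated gene had the same dispersion (0.000482), so extra spread of single genes between pairs was left out. The values for the block, which leaves 2 residual degrees of freedom per gene, may therefore look better than in the real libraries. The word search described in the closing observations ranked a planted 7-base word at place 1 in a simulation on 13824 genes. The planted shift was -0.2 on the log2 scale in the 1471 genes with that word, and smaller shifts were not simulated.

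Alternatives covered the pseudocount (2 and 40), the filter (none, or a mean of at least 100), rescaling by the median of ratios, by the upper quartile or by quantiles, robust empirical Bayes, the replicate block, a minimum log2 fold change of 0.58 either way (just under 1.5-fold) and each library left out in turn. Leaving out both libraries of a replicate number, leaving out pairs within the block, a correction for GC content and transcript length, and joint settings with the block were added after seeing the data. Count models were planned only for whole reads and were not run.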

Results

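The series measured the polyadenylated RNA of EndoC-βH1 cells, a human line that makes insulin, after transfection with a negative control siRNA (3 libraries) or with siRNA against STAT3 (3 libraries). The question in the series' own design is how the mRNA profile of a β-cell differs once STAT3 is knocked down. Values are given per 20000000 (20 M) counts in genes, with the SD over 3 libraries. The estimated depth was 22.74 to 27.64 M reads in the control libraries and 23.91 to 35.57 M in the STAT3 siRNA libraries. For control library 3, taken at 22.74 M, a depth of 42.74 M was a second candidate. On the first principal component, which held 66.2% of the variance, both libraries of replicate 2 stood apart from the other 4. The second component, with 17.2%, separated the siRNA groups.

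STAT3 itself was 2488, 2707 and 2394 in control libraries 1, 2 and 3 and 479, 430 and 579 in STAT3 siRNA libraries 1, 2 and 3, so every library matched its label. The gene (ENSG00000168610; GRCh38 chromosome 17, 42313324 to 42388568, minus strand) fell from 2529.7 ± 160.6 (SD, n = 3) to 496.0 ± 75.9 (SD, n = 3), a log2 fold change of -2.34 (SE 0.12; limma adjusted p = 0.0014) and 0.198 of the control level. The change was -2.35, -2.63 and -2.03 in pairs 1, 2 and 3. STAT1, the closest relative in the cytokine pathway, was 1678.3 ± 95.6 in controls and 1499.3 ± 124.0 with STAT3 siRNA. Its log2 fold change of -0.16 (SE 0.08) did not pass (limma adjusted p = 0.486), but passed with the replicate block (adjusted p = 0.0227, lower in 3 of 3 pairs). STAT1 overlaps GLS on the opposite strand.

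**Figure D1:**
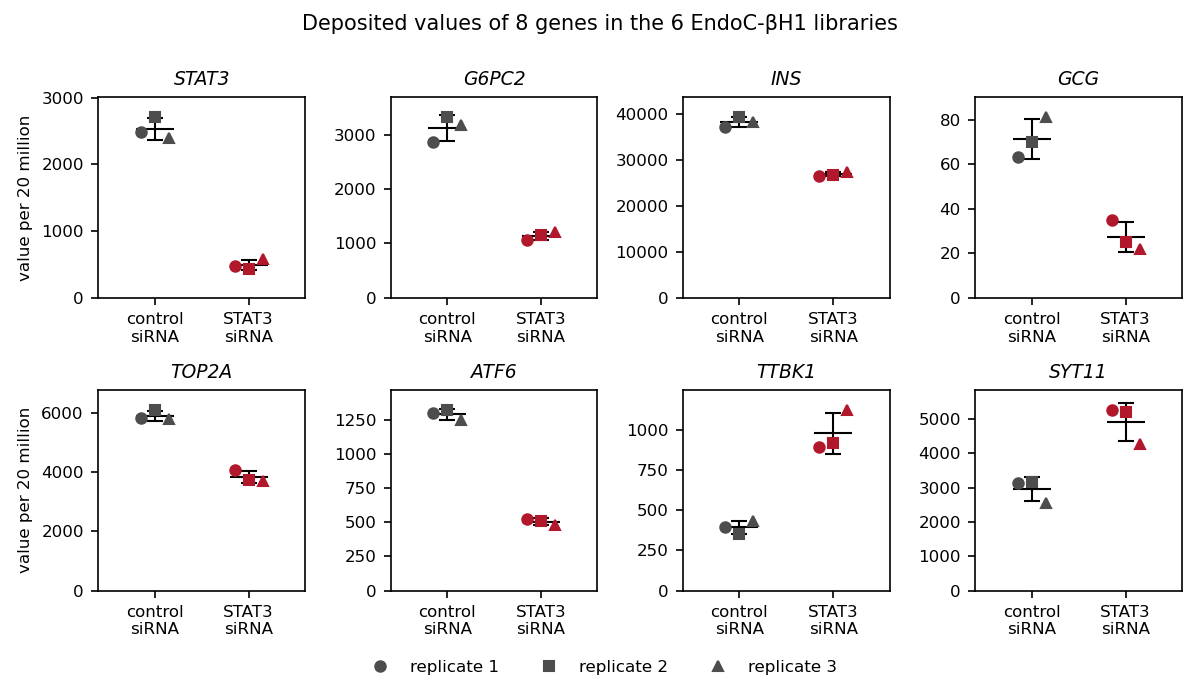
Deposited values per 20 M (vertical axes, from 0) of 8 genes in the 3 control siRNA (grey) and 3 STAT3 siRNA (red) libraries, with a marker shape per replicate number, a bar at the mean and whiskers of 1 SD. STAT3 lies between 430 and 579 in the STAT3 siRNA libraries and between 2394 and 2707 in the controls, and INS between 26481 and 27367 against 37050 to 39202.

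Of 20799 genes tested, 357 differed between the groups, 111 of them higher and 246 lower with STAT3 siRNA. With the replicate number as a block, 4838 genes passed, 2664 higher and 2174 lower. These included all 357, and 4348 of the 4838 differed by less than 1.5-fold. Each pair holds 1 library of each group, so the block leaves fold changes as they were and could not turn a direction. In 4768 of the 4838 all 3 pairs moved the same way, which passing a paired fit itself favours. The share of lower genes was 68.9% without the block, 44.9% with it, and 53.3% with the block after rescaling by the median of ratios. The count without the block fell to 6, 173 and 19 when control library 1, 2 or 3 was left out, and to 5, 4 and 21 without STAT3 siRNA library 1, 2 or 3. Without both libraries of replicate 2 it was 53. Of 86 genes named besides STAT3, 47 passed. With a single library left out between 3 and 36 of these 47 still did, while all 47 passed in the block and in the block with any pair left out. The block leaves 2 residual degrees of freedom per gene, and fewer with a pair left out. Its calls therefore lean on the spread pooled over genes, and a gene's own spread between pairs counts for little. MT-ND3, for one, passed in the block (adjusted p = 0.0108) with changes of -1.289, -1.067 and 0.263 in pairs 1, 2 and 3. When all genes above 0 in any library were tested, 13 of the 47 no longer passed: CX3CL1, FAIM2, FN1, GCG, INS, MAP1B, MSMO1, PPP1R15A, SV2A, SYT11, TUBB3, TXNIP and ZCCHC12. Of the named genes, RSAD2, ERAP1, ANXA4, PFKM, MAP1LC3B, HSPD1, PRKRA, HLA-A, MX1 and BCL2L1 overlap genes on the opposite strand, and ENO2 and CD68 overlap genes on their own strand, beside those said below to do so.

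Among genes past the threshold with a mean of at least 100 per 20 M, the 12 largest rises lay between 2.01-fold and 2.46-fold. TTBK1, which encodes a neuronal kinase of tau and tubulin (chromosome 6, 43243680 to 43288259, plus strand), rose from 392.3 ± 42.1 to 976.7 ± 125.5 (SD, n = 3 each), a log2 fold change of 1.29 (SE 0.12; limma adjusted p = 0.0102). SNAP91, a clathrin adaptor of synapses, rose from 210.0 ± 5.0 to 456.7 ± 18.8, and ATCAY, the neuronal protein caytaxin, from 274.0 ± 42.9 to 634.7 ± 34.6. SLC6A17, an amino acid transporter of synaptic vesicles, rose by 1.17 on the log2 scale and ASTN1, which acts in the migration of neurons, by 1.15. PIFO (1.30) and CCDC113 (1.14), which belong to cilia, rose as well. The other 5 of the 12 largest rises were PNMA8C (1.15), ZCCHC12 (1.10), NACAD (1.03), FAIM2 (1.01) and RNF112 (1.01). The 12 adjusted p-values lay between 0.0085 and 0.0321 in limma. Each gene was higher in 3 of 3 pairs, which follows from the rule that the groups do not overlap. SLC6A17, CCDC113 and RNF112 overlap genes on the opposite strand, whose reads cannot be told apart while the strand setting is unknown. FAIM2 and ZCCHC12 did not pass after quantile normalization.

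After STAT3, the largest falls among such genes were in ZNF252P, a transcribed pseudogene, and in G6PC2, the glucose-6-phosphatase subunit of islets. ZNF252P (chromosome 8, 144973589 to 145002895, minus strand) fell from 1095.7 ± 78.1 to 386.3 ± 8.1 and G6PC2 (chromosome 2, 168901240 to 168910000, plus strand) from 3125.7 ± 233.7 to 1141.0 ± 74.1 (SD, n = 3 each). Their log2 fold changes were -1.48 (SE 0.08; limma adjusted p = 0.0014) and -1.45 (SE 0.08; adjusted p = 0.0018). G6PC2 overlaps SPC25 on the opposite strand. ATF6, a sensor of endoplasmic reticulum stress, fell to 0.396 of its control level (505.3 ± 25.4 against 1291.3 ± 38.6). The imprinted noncoding RNA H19 fell to 0.410 of it, and H19_1, a short annotated RNA inside H19 on the other strand, to 0.391, with reads that cannot be assigned to either strand. HIST1H2BL (-1.24), a histone gene with near-identical copies that may share its reads, CRYBA2 (-1.23), a crystallin, and HMGB2 (-1.21), a chromatin protein of dividing cells, fell too. So did NT5E (-1.21), which makes extracellular adenosine, PIGS (-1.17), part of the GPI anchor transamidase, and MARVELD2 (-1.16), a tight junction protein. PIGS overlaps AC005726.2 on the same strand. The 7-base word GAATTCA, which marks lower genes across this table, occurs 3 times in the 3' UTR of ATF6 and 1 time each in those of HMGB2, NT5E, PIGS and MARVELD2. It is absent from the 3' UTRs of G6PC2, HIST1H2BL and CRYBA2, and the noncoding ZNF252P, H19 and H19_1 were not searched. Of other named genes, FAIM2, SYT11 and BMF, which rose, hold 1 copy each, as do PARP14, which was higher in the block alone, ERAP1, which was lower in the block alone, and BCL2L1, which passed in neither fit.

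Insulin mRNA was lower. INS (chromosome 11, 2159779 to 2161341, minus strand) fell from 38116.7 ± 1076.1 to 26856.3 ± 458.2 (SD, n = 3 each), a log2 fold change of -0.50 (SE 0.08; limma adjusted p = 0.0284) and lower in 3 of 3 pairs. It did not pass after rescaling by the median of ratios or the upper quartile without the block, and passed in every blocked fit. INS shares its strand and exons with the readthrough gene INS-IGF2. Of the 41 tested genes for insulin production and stimulus-secretion coupling, 0 were higher and 2 lower (INS and G6PC2), the same 2 when adjusted over the list alone, and 4 higher and 9 lower with the block. Fry gave the list an adjusted p of 0.0173 one way but 0.103 in the block, and camera gave 0.138 at the preset correlation and 0.638 with an estimated one. IAPP, the amyloid peptide secreted with insulin, had values of 1308.7 ± 466.4 and 1960.0 ± 578.0 (log2 fold change 0.59, SE 0.29; adjusted p = 0.443, but 1.19e-05 in the block).

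Among other islet hormones, GCG, which encodes glucagon (chromosome 2, 162142873 to 162152404, minus strand), fell from 71.3 ± 9.1 to 27.3 ± 6.8 (SD, n = 3 each), a log2 fold change of -1.13 (SE 0.20; limma adjusted p = 0.0435). SST, the somatostatin gene, had a log2 fold change of -0.16 (SE 0.07; adjusted p = 0.353, and 0.0294 in the block). Of 14 tested genes of this list 0 were higher and 1 lower, with 5 lower when adjusted over the list alone and 8 lower in the block. Their median log2 fold change was -0.31. Camera gave the list an adjusted p of 4.49e-05 at the preset correlation and 0.196 with an estimated correlation, and fry gave 0.00665 (0.0344 in the block).

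None of the 27 tested β-cell transcription factors and identity genes passed, over all genes or when adjusted over the list alone. With the block 3 were higher and 11 lower. ESRRG had a log2 fold change of -0.64 (SE 0.14; limma adjusted p = 0.0715, and 3.78e-05 in the block), and INSM1, a factor of endocrine cells, -0.40 (SE 0.10; adjusted p = 0.117, and 4.48e-05 in the block). PDX1, a master factor of the pancreas, was 10435.7 ± 777.3 in controls and 10260.0 ± 743.8 with STAT3 siRNA, a log2 fold change of -0.02 (adjusted p = 0.997) that had no steady sign when single libraries were left out. NKX6-1 was at 0.38 (SE 0.17; adjusted p = 0.409, and 4.35e-05 in the block) and MAFA at -0.18 (SE 0.20; adjusted p = 0.861, and 0.0109 in the block). The list as a whole had a camera adjusted p of 0.00347 at the preset correlation and 0.638 with an estimated correlation, with a median of -0.06. At the preset correlation it did not pass without control library 2 (0.0783) or without STAT3 siRNA library 1 (0.134).

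Of 32 tested cell cycle genes, 0 were higher and 14 lower, with 24 lower when adjusted over the list alone and 28 lower and 1 higher in the block. TOP2A, the topoisomerase of dividing cells, fell from 5910.3 ± 170.6 to 3847.0 ± 201.9 (SD, n = 3 each), a log2 fold change of -0.62 (SE 0.07; limma adjusted p = 0.0183). RRM2, a subunit of the enzyme that makes deoxynucleotides, fell by 0.72 on the log2 scale, AURKA, a mitotic kinase, by 0.61 and MCM3, a helicase subunit, by 0.60, each in 3 of 3 pairs. RRM2 overlaps AC007240.1 on its strand, and the 3' UTR of MCM3 holds 1 copy of GAATTCA. The list's median log2 fold change was -0.43, and -0.36, -0.48 and -0.45 in pairs 1, 2 and 3. Camera gave an adjusted p of 6.24e-25 at the preset correlation and 0.239 with an estimated correlation, and fry gave 0.0155 (0.0494 in the block). The count of lower members was 6 without control library 2 and 0 without any other single library or without both libraries of replicate 2, where the median was -0.38.

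Of 15 tested genes that are normally kept low in mature β-cells or mark progenitors, 0 were higher and 3 lower, with 1 higher and 7 lower when adjusted over the list alone and the same in the block. ID1 fell from 515.7 ± 110.3 to 224.0 ± 21.5 (SD, n = 3 each; log2 fold change -1.15, SE 0.16; limma adjusted p = 0.0218). ID3 fell by 1.04 on the log2 scale, and CXCL12, a chemokine gene, by 0.60. ID1 and ID3 encode inhibitors of basic helix-loop-helix factors. The list's camera adjusted p was 4.49e-05 at the preset correlation and 0.638 with an estimated correlation, and fry's was 0.133 but 0.0494 in the block.

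Of 31 tested genes of the extracellular matrix, adhesion and the cytoskeleton, 0 were higher and 4 lower, with 5 lower when adjusted over the list alone and 8 higher and 12 lower in the block. FN1 (fibronectin) fell from 814.0 ± 187.2 to 421.7 ± 5.1 and CDH1 (E-cadherin) from 2174.7 ± 243.1 to 1204.3 ± 140.9 (SD, n = 3 each). LAMB1 fell by 0.53 on the log2 scale and ITGA6 by 0.55, with limma adjusted p-values of the 4 genes between 0.0183 and 0.0354. LAMB1, CDH1 and ITGA6 overlap genes on the opposite strand, and the 3' UTR of CDH1 holds 1 copy of GAATTCA. The list did not pass camera (adjusted p = 0.128) or, without the block, fry's test of a common direction (0.133, but 0.0494 in the block).

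Tubulins, stathmins and microtubule regulators held 4 higher and 0 lower genes among 28, with 9 higher and 3 lower when adjusted over the list alone and 12 higher and 5 lower in the block. TUBB3, the tubulin of neurons, rose from 3507.3 ± 379.5 to 5554.0 ± 422.4 (SD, n = 3 each; log2 fold change 0.66, SE 0.10; limma adjusted p = 0.0287). It overlaps AC092143.1 on the same strand. The kinesin KIF5A (0.53) and the microtubule-associated MAP1A (0.60) and MAP1B (0.60) rose too, with MAP1A not passing after upper-quartile rescaling. The list did not pass camera (adjusted p = 0.138). Of 30 genes of secretory granules and exocytosis, 2 were higher and 0 lower, with 3 higher when adjusted over the list alone and 12 higher and 5 lower in the block. These were SYT11 (2955.7 ± 357.6 to 4906.3 ± 556.4; adjusted p = 0.0354), a synaptotagmin, and SV2A (957.3 ± 78.7 to 1438.7 ± 116.5; adjusted p = 0.0321), a vesicle glycoprotein. Neither passed without the block after rescaling by the median of ratios or the upper quartile. The granule list did not pass camera (adjusted p = 0.275), and passed fry's test of a common direction in the block (0.0494) but not without it (0.254).

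**Figure D2:**
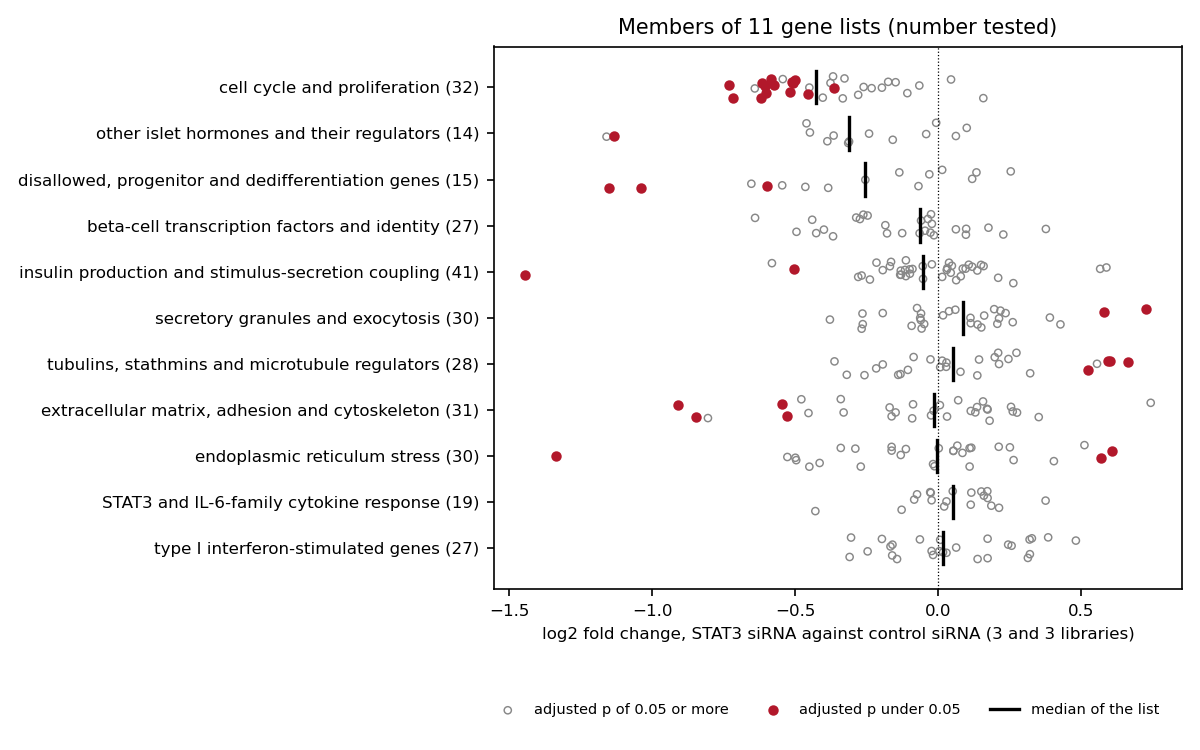
Log2 fold change of every tested member (horizontal axis, STAT3 siRNA against control siRNA, n = 3 libraries each) of 11 gene lists, with filled points for genes at an adjusted p under 0.05, open points for the others and a bar at each list's median. Of the 32 cell cycle genes 14 are filled, all to the left of 0, and 4 filled tubulin and microtubule genes lie to the right.

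Among 30 endoplasmic reticulum stress genes, 2 were higher and 1 lower, with 6 higher and 7 lower when adjusted over the list alone and 7 higher and 10 lower in the block. ATF6 was the lower one. TXNIP, an inhibitor of thioredoxin, rose from 327.0 ± 21.6 to 504.3 ± 42.1 and PPP1R15A (GADD34) from 509.7 ± 52.3 to 760.3 ± 29.7 (SD, n = 3 each; limma adjusted p = 0.0321 and 0.0349), the latter not after rescaling by the median of ratios or the upper quartile. Of 29 genes of the BCL2 family and apoptosis, 1 was higher and 0 lower, with 1 higher and 3 lower when adjusted over the list alone and 5 higher and 6 lower in the block. BMF, which promotes apoptosis, rose from 1128.3 ± 6.8 to 1545.7 ± 60.7 (adjusted p = 0.0241), not after upper-quartile rescaling, and it overlaps AC021755.2 on the opposite strand. BCL2L1, an inhibitor of apoptosis, had a log2 fold change of -0.06 (SE 0.07; adjusted p = 0.886). Of 25 genes of cholesterol synthesis, 0 were higher and 1 lower, as when adjusted over the list alone, and 2 higher and 7 lower in the block. That gene, MSMO1, fell from 1402.7 ± 209.8 to 822.0 ± 89.6 (adjusted p = 0.0406) and holds 2 copies of GAATTCA in its 3' UTR. These 3 lists did not pass camera (adjusted p = 0.374, 0.624 and 0.138).

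None of the 19 tested targets of STAT3 and IL-6-family cytokines passed, over all genes or when adjusted over the list alone, with 2 higher and 1 lower in the block. KLF6 was at 0.17 (SE 0.10; limma adjusted p = 0.519) and SBNO2 at 0.16 (SE 0.09; adjusted p = 0.534, and 0.0406 in the block). SOCS3, a classical STAT3 target, lay between 0 and 2 in the 6 libraries and was not tested, as was CXCL10, between 0 and 1. None of 36 JAK-STAT receptors, kinases and STATs passed, over all genes or adjusted over the list alone, with 10 higher and 4 lower in the block. IL6ST, the shared receptor of the IL-6 family, was 809.3 ± 90.6 and 538.3 ± 83.8 (adjusted p = 0.0924, and 2.77e-06 in the block), and LIFR 76.7 ± 8.4 and 46.7 ± 3.2 (adjusted p = 0.112, and 0.00215 in the block). The 3' UTR of IL6ST holds 4 copies of GAATTCA and that of LIFR 1 copy, and both overlap genes on the opposite strand. The camera adjusted p was 0.505 for each of these lists. Fry's test of change in either direction gave 0.533 for the targets (0.00561 in the block) and 4.93e-05 for the JAK-STAT list (0.00268 in the block).

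None of 27 type I interferon-stimulated genes and none of 21 HLA class I genes passed, over all genes or adjusted over the list alone, with 3 higher and 4 lower and with 1 higher and 8 lower in the block. PARP14 was at 0.48 (SE 0.13; limma adjusted p = 0.140, and 0.00456 in the block), RSAD2 at -0.30 (SE 0.10; adjusted p = 0.195, and 0.0181 in the block) and MX1 at 0.32 (SE 0.18; adjusted p = 0.517). HLA-E was at -0.34 (SE 0.11; adjusted p = 0.213, and 4.29e-05 in the block) and ERAP1 at -0.27 (SE 0.07; adjusted p = 0.103, and 0.00159 in the block). HLA-A was at -0.05 (SE 0.14; adjusted p = 0.986), with no steady sign when single libraries were left out. The camera adjusted p was 0.982 and 0.252. Of 21 genes of chemokines, cytokines and the NF-kB response 1 was higher and 0 lower, with 2 higher when adjusted over the list alone and 6 higher in the block (camera adjusted p = 0.138; fry's test of a common direction 0.156, but 0.0494 in the block). CX3CL1, the chemokine fractalkine, rose from 643.3 ± 33.3 to 928.3 ± 84.9 (adjusted p = 0.0406), but did not pass without the block after rescaling by the median of ratios or the upper quartile.

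The 13 mitochondrially encoded genes differed widely between libraries of one group. They took 0.35%, 0.57% and 0.71% of control libraries 1, 2 and 3 and 0.16%, 0.37% and 0.77% of STAT3 siRNA libraries 1, 2 and 3. Their median log2 change was -1.35 and -0.79 in pairs 1 and 2 and 0.17 in pair 3. None passed, over all genes or adjusted over the list alone. All 13 were lower in the block, and 0 in the block with robust empirical Bayes. MT-CO1 was 24726.7 ± 5031.0 and 19637.7 ± 8845.7 (SD, n = 3 each; limma adjusted p = 0.733), and MT-ND3 1347.0 ± 464.3 and 1032.7 ± 902.7 (adjusted p = 0.768). Both passed in the block (0.00627 and 0.0108) but not in the block with robust empirical Bayes. Camera gave the list 0.027 at the preset correlation and 0.868 with an estimated correlation. At the preset correlation it did not pass without control library 2 (0.129) or 3 (0.165), after rescaling by the median of ratios (0.0501) or without STAT3 siRNA library 1, where it turned upward (0.911). None of 33 nuclear-encoded genes of oxidative phosphorylation, 34 cytosolic ribosomal proteins, 28 genes of glycolysis and hypoxia, 30 of autophagy and the lysosome or 21 immediate-early and heat-shock genes passed, over all genes or adjusted over the list alone. With the block 0 to 7 members of each were higher and 0 to 3 lower. The smallest adjusted p-values in these lists belonged to UQCRC2 (0.467), COX5A (0.497), RPL37A (0.457), RPLP1 (0.575), PFKM (0.121), ENO2 (0.230), MAP1LC3A (0.151), MAP1LC3B (0.192), JUN (0.151) and HSPD1 (0.425). In the block COX5A (0.0401), PFKM (0.000573), ENO2 (0.00504), MAP1LC3A (0.00436), MAP1LC3B (0.000134), JUN (0.0015) and HSPD1 (0.0114) passed. Camera gave these 5 lists adjusted p-values between 0.231 and 0.848.

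Genes of other cell types were few. Of 30 listed exocrine and ductal markers 12 were tested and 0 passed (camera adjusted p = 0.221), with 1 higher and 4 lower in the block. CPA1, an acinar peptidase, was 801.0 ± 102.1 and 648.3 ± 70.4 (limma adjusted p = 0.327), and ANXA4 was at -0.28 (SE 0.10; adjusted p = 0.285). Of 14 fibroblast and mesenchymal markers 3 were tested, as were 3 of 16 endothelial and leukocyte markers. None passed over all genes, and COL1A1 was higher when adjusted over the list alone. COL1A1 was 67.0 ± 15.1 and 105.7 ± 7.4 (adjusted p = 0.161), S100A4 at -0.37 (0.615), CD68 at -0.20 (0.616) and CD14 at -0.20 (0.807). In the block CPA1 (0.00134), ANXA4 (0.00613), COL1A1 (0.00124), S100A4 (0.00804) and CD68 (0.0145) passed. Of 15 genes of the RNA interference machinery 0 passed over all genes, 2 were higher and 2 lower when adjusted over the list alone, and 4 were higher and 6 lower in the block (camera adjusted p = 0.560). AGO1 was 4375.3 ± 392.8 and 5938.0 ± 310.8 (adjusted p = 0.0566, and 5.6e-06 in the block), and PRKRA was at -0.29 (SE 0.08; adjusted p = 0.125, and 0.000779 in the block), with 2 copies of GAATTCA in its 3' UTR.

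Of the 24 lists with at least 5 tested members, camera at the preset correlation called 5 shifted, all downward with the 6 libraries. These were the lists of cell cycle genes, of other islet hormones, of disallowed and progenitor genes, of β-cell transcription factors and of mitochondrially encoded genes. The first 3 of these passed in each of 25 alternative settings at that correlation, and the other 2 did not. With the correlation estimated per list 0 passed. Fry's test of a common direction called 3: the cell cycle (0.0155), other islet hormones (0.00665) and insulin production (0.0173). With the block fry called 6: other islet hormones (0.0344) and, each at 0.0494, the cell cycle, disallowed and progenitor genes, the extracellular matrix, chemokines and secretory granules, but not insulin production (0.103). Fry's test of change in either direction, which does not compare a list with other genes, called 16 of the 24 lists, and 21 with the block, the same 16 among them. Its smallest adjusted p-values without the block were 4.73e-06 for secretory granules, 9.15e-06 for the BCL2 family and 1.1e-05 for endoplasmic reticulum stress. The 9 other ways of splitting the 6 libraries into 3 and 3 gave 4 to 15 lists at the preset correlation.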

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

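Alternatives that leave out pairs, both libraries of a number, or that join the block with another setting, and the correction for GC content and length, were chosen after seeing the data. STAT3 was lower under every setting and passed in all except without replicate 1 (both libraries), where the STAT3 log2 fold change was -2.33 with an adjusted p of 0.298, on 2 libraries per group. It ran from -2.45 to -2.24 without a single library and was -2.19 and -2.49 without both of replicate 2 and 3. Changed genes numbered 178 with no filter on low values (43 higher, 135 lower), 545 (187 higher) with a mean of at least 100, and 216 (71 higher, 145 lower) at a log2 fold change of at least 0.58 either way. Higher genes numbered 67 and 66 after rescaling by the median of ratios and the upper quartile. The replicate block gave 4838 (2664 higher, 2174 lower). With a pair left out it gave 5232 (2905, 2327), 3340 (1677, 1663) and 2635 (1383, 1252) without pairs 1, 2 and 3. It gave 4676 (2183, 2493) with the median of ratios, 4888 (2719, 2169) with robust empirical Bayes, 4972 (2634, 2338) with GC content and length trends removed, and 507 (224 higher) at a log2 fold change of at least 0.58. That cutoff lies just under the exact 1.5-fold used above for the 4348 genes with smaller changes, so the 2 counts overlap slightly. With single libraries left out the count ran from 4 to 173, with 0 to 52 higher and 4 to 121 lower. Without both libraries of replicate 1, 2 and 3 it was 0, 53 and 1, with 0, 16 and 0 higher and 0, 37 and 1 lower, while 1526, 2583 and 2115 genes had an unadjusted p under 0.05 in limma, against 2874 with all libraries. Fewer libraries leave limma fewer degrees of freedom, and the cause of the other differences was not tested.

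Shifted lists numbered 4 to 8 with single libraries left out, 8 of them without STAT3 siRNA library 3. At the preset correlation 3 of the 5 kept their call in all 25 settings: the cell cycle, other islet hormones and disallowed genes. The β-cell factors lost it without control library 2 (adjusted p = 0.0783) and STAT3 siRNA library 1 (0.134). The mitochondrial list lost it without control library 2 (0.129), control library 3 (0.165) and STAT3 siRNA library 1 (0.911, upward), without both libraries of replicate 1 (0.077) or 2 (0.154), after rescaling by the median of ratios (0.0501) and after the GC content and length correction (0.0612). A further 10 lists passed in 1 to 5 settings. With a single library left out these were the extracellular matrix without control library 1; granules, nuclear-encoded oxidative phosphorylation, tubulins and autophagy without control library 2; stress of the endoplasmic reticulum and cholesterol without control library 3; cholesterol, then insulin production and the extracellular matrix, then oxidative phosphorylation, tubulins and autophagy without STAT3 siRNA library 1, 2 and 3. Shifted lists were 0 with an estimated correlation, with or without the block, 3 by fry's test of a common direction and 6 by that test with the replicate block, where the cell cycle and other islet hormones passed in both and insulin production without the block alone. The PDX1 log2 fold change reversed to 0.04 without control library 2 and 0.03 without STAT3 siRNA library 1, and was -0.07 at its lowest, without STAT3 siRNA library 2. The HLA-A log2 fold change reversed to 0.02 without control library 2, 0.09 without STAT3 siRNA library 3, 0.02 without both libraries of replicate 3 and 0.02 in the block without pair 3, was -0.16 at its lowest, without STAT3 siRNA library 1, and the cause was not tested. Of 47 named genes past the threshold besides STAT3, 34 still passed without the filter, 42, 40 and 45 after the 3 rescalings, 46 of the 81 still tested at a mean of at least 100, and 47 with either other pseudocount, robust empirical Bayes or the block. The block added 30 calls and could turn no direction, since it leaves fold changes as they were. The tests on whole reads that were planned (a quasi-likelihood test with and without the block, and a second count model) were not run, since whole reads could not be recovered. Rounding to whole units limits genes with values near 0, and the simulated recovery of 12% at 1.5-fold limits what the fit without a block can call.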

Other observations

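The lists in this part beyond those fixed in advance, the search by following base, the test of histones against other RNAs without a poly(A) tail and the test of words that mark higher genes were chosen after the results were seen.

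Of 58 tested replication-dependent histone genes, 0 were higher and 33 lower with STAT3 siRNA (limma), 54 lower in the block, with a median log2 fold change of -0.61. The median was -0.42, -0.74 and -0.69 in pairs 1, 2 and 3. They took 0.472%, 0.567% and 0.505% of control libraries 1, 2 and 3 and 0.354%, 0.339% and 0.327% of STAT3 siRNA libraries 1, 2 and 3. The 33 fell to 26 and 25 after rescaling by the median of ratios and the upper quartile, rose to 45 after quantile normalization, and were 24 without control library 2 and 0 or 1 without any other single library. The list was drawn up after HIST1H2BL had been seen among the falls and includes it. Histone genes have near-identical copies that may share reads. Of 31 other RNAs without a poly(A) tail 0 passed, with 2 higher and 15 lower in the block and a median of -0.21, and -0.36, -0.21 and -0.08 in pairs 1, 2 and 3.

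Of 51 tested genes of motile cilia and the axoneme, 49 had a positive fold change, with a median of 0.33, and 0.24, 0.40 and 0.36 in pairs 1, 2 and 3. Over all genes 1 passed, DRC1 (1.33, SE 0.21; limma adjusted p = 0.0306; named after its values were seen), 0 without any single library, and 33 were higher and 1 lower in the block. This list was drawn up after PIFO and CCDC113 had been seen among the largest rises and leaves both out. Of 14 inhibitors of differentiation and genes of BMP signalling, not all of them targets of that pathway and 3 of which also stand in a fixed list, 0 were higher and 5 lower, with a median of -0.31, and 1 was higher and 7 lower in the block. The 5 lower were 3 without control library 2, 1 without STAT3 siRNA library 3 and 0 without any other single library. These 5 were ID1, ID3, ID4 (-0.59), GREM1 (-0.74) and ACVR1 (-0.76), the last 3 named after their values were seen, and the 3' UTRs of GREM1 and ACVR1 hold 3 and 1 copies of GAATTCA. The list was drawn up after ID1 and ID3 had been seen to fall, so that its values in part repeat theirs. Of its 12 other genes 0 were higher and 3 lower, 1 higher and 5 lower in the block, with a median of -0.22 and an unadjusted camera p of 0.0417 with an estimated correlation (0.0684 in the block). With an estimated correlation the adjusted p of camera over the 5 added lists was 0.0468 for the histones, the cilium genes, the BMP signalling genes and the neuronal genes, and 0.0574 for the RNAs without a poly(A) tail, but 0.117 for all 5 in the block.

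Of 32 cell cycle genes 14 were lower and 0 higher with STAT3 siRNA, 30 had a negative fold change, and the list passed camera at the preset correlation (adjusted p = 6.24e-25) but not with an estimated one (0.239, and 0.554 in the block). In pair 3 the list's median log2 change was -0.447 (SE over genes 0.052), with 23.91 M reads in the STAT3 siRNA library against 22.74 M, or 42.74 M as the second candidate, in the control library, and since the control library was the shallower one in pairs 1 and 2 (26.15 and 27.64 M against 35.57 and 34.58 M), unequal depth is argued against at either value. The median was -0.429 in the paired fit after correction for GC content and length and -0.379 without the pair of replicate 2, which stands apart. It was -0.389 over the 30 members whose 3' UTR lacks the word GAATTCA. A GC content or length trend, the pair of replicate 2 and direct matches to GAATTCA therefore do not account for the lower median of the list. Of 6 words that marked lower genes beyond the shuffles described below, only GAATTCA was checked for this list. The others all overlap it in sequence and are not separate findings. Matches to them without the whole of GAATTCA stay open. For the histone genes the difference of medians from other RNAs without a poly(A) tail was -0.06 (SE over genes 0.085) in pair 1 and -0.529 and -0.603 in pairs 2 and 3 (-0.554, SE over genes 0.059, over both). This argues, on 2 pairs only, against a lower carry-over of such RNAs as the whole cause there, and leaves it open in pair 1. SEs over genes treat genes as independent. The estimated correlation was 0.307 between cell cycle genes and 0.62 between histone genes, so these SEs are too small. A slower cell cycle after STAT3 siRNA may be the source of the lower median, as a hypothesis found on these same libraries and not tested. Whether it would follow from the loss of STAT3 or from the silencing of another gene was not tested either.

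Falls of genes other than STAT3 may in part come from silencing by the siRNA through short matches in 3' UTRs. Among 16233 words of 7 bases in the 3' UTRs of 13824 genes, GAATTCA marked lower genes with a z of -16.52, against -4.47 for the lowest word in 100 shuffles, and 81 of 214 lower genes (37.9%) held it against 12.9% of all genes and 11 of 105 higher genes (10.5%). The median log2 fold change of genes with the word differed by -0.09 from that of genes with similar 3' UTRs. Genes with 2 or more copies lay below genes with 1 copy by a difference of medians of -0.052 (permutation p = 0.00052, two-sided). Neither this permutation nor the shares above matched genes by the length or base content of their 3' UTRs, so copy number is not parted from these. STAT3 holds the word 1 time, in the coding sequence of exon 13 (GRCh38 chromosome 17, 42329562 to 42329568, minus strand), followed by A, and across the table the carriers of GAATTCAA had the lowest median (-0.093, against -0.026 to -0.052 with another following base), although a given word of 7 bases is expected 0.31 times by chance in a transcript of 5047 bases. Over all genes the fold change followed GC content and transcript length only weakly (Spearman correlation 0.043 and 0.076). The 245 lower genes kept a median of -0.608 (SE over genes 0.017) after such trends were removed. They were picked as lower from the same libraries, so their median is not an independent test. In all, 6 words lay below the lowest shuffle, with AATTCAA (z -11.48) next after GAATTCA. The rest were TGAATTC, AATTCAT, AGAATTC and ATTCAAA. All of these share a run of bases with GAATTCA, so they do not stand for separate sites. The next word down, GCGTGCC (z -4.29), lay within the shuffles. Of the 214 lower genes 133 lack GAATTCA. For these, G6PC2, HIST1H2BL and CRYBA2 among them, matches to other words or outside the 3' UTR, loss of STAT3 and indirect effects stay open.

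Of 45 tested genes in an added neuronal list, 0 passed over all genes or when adjusted over the list alone, 36 had a positive and 9 a negative fold change, 19 were higher and 5 lower in the block, and camera with an estimated correlation called the list without the block (0.0468) and not with it (0.117). The list leaves out TTBK1, SNAP91, ATCAY, SLC6A17 and ASTN1, neuronal or synaptic genes among the largest rises that did pass. The list's median was 0.126 (SE over genes 0.050) after correction for GC content and length, against 0.169 before, so that such a bias cannot be told apart from the rest at this size. A large fall in the mRNA of REST, which represses neuronal genes, is argued against by its log2 fold change of 0.015 (SE 0.109) in the paired fit. A small fall lies within that spread, and REST protein was not measured, so lower REST activity stays open. Silencing by the control siRNA through short matches stays open, since 5 words marked higher genes beyond the shuffles (highest z 4.88, against 4.58) and the 23 neuronal genes without any of these words had a median of 0.177 (SE 0.082), against 0.111 for the 22 with at least 1, a spread too wide to decide. Whether the list as a whole differs, and from what cause, stays open, with the loss of STAT3 as an untested biological one.

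The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes changed, higher and lower, 1 of the 10 splits, the real one, gave as many, with 357, 111 and 246 genes against 0, 0 and 0 as the highest of the others. For shifted lists 9 of the 10 splits gave as many, with 5 in the real split and 15 as the highest of the others. The 4 splits that keep the libraries of replicate 2 together gave 8, 10, 15 and 15 lists and the other 5 gave 4, 5, 6, 10 and 10, so that splits other than the real one also move lists at the preset correlation. Of the 4 splits that part all 3 pairs, the blocked fit called 4838 genes in the real one and 0 in each of the other 3, and 5 lists against 5, 3 and 3.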
